A study of Arabidopsis thaliana with 4 samples.

How the data were processed

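The data were 4 one-colour Affymetrix arrays of *Arabidopsis thaliana*, accession Columbia, on which biotin-labelled material from total RNA of imbibed seeds had been hybridised. Seeds had been kept for 3 days on agar medium with trichostatin A (TSA, an inhibitor of histone deacetylases) or without it. The labels give 2 arrays to each group and describe the replicates as coming from separate treatments. The labels disagree on the dose: one field gives 10 micromolar and another 10 mM, so the dose is not settled here. The deposited table holds 1 intensity per probe set and array on a linear scale, made by the authors with MAS5 per the submitters' processing notes (the version is not given in the sources used here). In the deposited values the 2% trimmed means of the 4 arrays lay between 1502.56 and 1502.7, so the arrays had already been scaled to a common level. Detection calls were not used here, and a low signal is therefore not read as absence of the transcript.

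The array has 8297 probe sets, of which 50 control probe sets were left out of all tests. The remaining 8247 were brought to the mean of the arrays' 2% trimmed means, which moved almost nothing, and converted to log2. The 33.3% with the lowest mean log2 signal over all 4 arrays were left out, which kept 5498. Names came from the platform annotation through gene numbers and the TAIR10.1 gene table: 3794 probe sets named 1 gene, 70 named several and were not used as names, and 4383 were not listed and stay unnamed here. Genome coordinates were not used, since the files name no build. Probe sets whose identifier ends in _s_at or _f_at can read several members of a gene family, and their values are uncertain for a single gene (as for LTI30, COR47, LHB1B2, LHCB4.3, RCA, HIS1-3, HIS4, AT2G30620, EXGT-A3, TUA1, PRL, GSTF3 and AT1G30870).

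TSA was compared with untreated by limma 3.58.1 in R 4.3.3, with lmFit and eBayes with an intensity trend, two-sided, and Benjamini-Hochberg adjustment, at an adjusted p threshold of 0.05. The fit left 2 residual degrees of freedom. The labels do not say that a replicate number marks a shared day, so the fit had no replicate block, and a fit with it was an alternative. Control probe sets showed that the arrays fall into 2 batches by replicate number, each holding 1 array of either group. Values within each replicate pair are therefore given beside the gene lists. The differences between replicates 1 and 2 in the 2 groups correlated across the tested probe sets at r = 0.127 (genes are not independent replicates).

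Gene lists, 20 in number with 450 entries were fixed before the data were examined. Of these entries 63 had a probe set naming that gene alone and 57 passed the intensity filter. A gene with several probe sets was represented by the brightest. The 7 lists with at least 3 such members were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 7 lists. An estimated correlation was the alternative. A planned list of ribosomal proteins was not made, since the annotation used here carries no descriptions. The named genes followed a rule fixed at the same time: up to 12 genes in each direction whose 2 TSA arrays both lay on one side of both untreated arrays and whose brighter group reached the median signal of all probe sets (log2 8.52). As fewer than 5 genes passed the threshold, these were the ones with the smallest limma p. Up to 4 members with the smallest p were added from each tested list. HDA6 and HDA19, also in the rule, had no named probe set.

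The fit was tested on 100 simulated data sets with the real probe set means, in each of which 200 of 5498 probe sets had been changed. With each probe set's own moderated variance, 0.1% of 2-fold, 0.84% of 4-fold, 6.1% of 8-fold and 21.7% of 16-fold changes were recovered, and 11.9% of the calls were false on average, which is above the nominal share. With variances drawn from the prior that limma fits, the recovered share was 0% at every size. There, 0.06 unchanged probe sets per data set were called on average, so every call was false. Of unchanged probe sets, 4.9% and 5.03% had an unadjusted p under 0.05 in these 2 kinds of simulation. A list of 15 genes changed 2-fold was called by camera in 84 of 100 simulations with own variances, and 2.22% of 900 unchanged lists had p under 0.05. With prior variances these were 75 of 100 and 2.78%. These simulations draw genes independently, so they do not cover correlation between genes. For each list, the median within a replicate pair was also placed among 10000 random lists of the same size matched on mean signal. The alternatives were other scalings, other filters on dim probe sets, an offset of 50 on the signal, other variance models, the replicate block, leaving out each array in turn, another threshold, and the other choices for lists. The number of arrays limits the precision of every value.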

Results

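Transcript levels were measured in imbibed *Arabidopsis* seeds after 3 days on medium with TSA, which inhibits histone deacetylases, the enzymes that remove acetyl groups from histones, and on medium without it. The seeds were kept under 16 h of light on 0.8% agar. Each group had 2 arrays, from separate treatments. The median signal as deposited was 350.7 and 445 on TSA replicates 1 and 2, and 321.2 and 451.1 on untreated replicates 1 and 2.

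The comparison of TSA with untreated asks which transcripts differ when histone deacetylases are inhibited during imbibition. Late embryogenesis abundant (LEA) proteins and dehydrins, hydrophilic proteins that accumulate in maturing seeds and under desiccation, rose as a group in TSA. Of their 15 measured genes, 14 had the higher mean in TSA, and in 10 both TSA arrays lay above both untreated arrays. The median difference over the list was 2.62 on the log2 scale, or 6.16-fold. The camera test with a preset correlation gave an adjusted p of 2.5e-14 for the list, and the adjusted p was 0.387 with an estimated correlation (p = 0.0599), so that call is lost there. On all arrays no member passed limma's adjusted threshold over all probe sets tested, and 7 of 15 passed when adjusted over the list alone. That count rose without TSA replicate 2 and fell without any other array. A fit without 1 TSA array takes its spread from the 2 untreated arrays alone, so its calls do not show a replicated TSA effect. The median SD over probe sets was 0.45 between the untreated arrays and 0.69 between the TSA arrays. Within replicate pair 1 the list's median difference was 4.01, and within pair 2 it was 2.68, both at the percentile 100 of random lists matched on signal. Lists without a common shift also reached such extremes within a pair: photosystem genes lay at percentile 0 in pair 1 and 100 in pair 2, and Calvin cycle genes at 1.35 and 99.7. With the replicate number as a block the camera adjusted p was 5.7e-16. The log2 median was 2.09 without TSA replicate 1 and 4.05 without TSA replicate 2, against 2.62 on all arrays.

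Among the dehydrins, LTI30 (AT3G50970, also XERO2) was 9.23-fold higher in TSA, at log2 13.06 ± 0.03 against 9.85 ± 0.27 in untreated seeds (SD, n = 2). LEA4-5 (AT5G06760), of the LEA group 4 proteins, was 9.67-fold higher, at 14.86 ± 1.1 against 11.59 ± 0.54. The LEA genes AT3G17520, AT2G42560, AT3G15670 and AT4G36600 were 26.5-fold, 17.9-fold, 10.5-fold and 13.5-fold higher. The size of most of these depended on which TSA array was used: without TSA replicate 1 and without TSA replicate 2, the log2 difference was 3.47 and 5.99 for AT3G17520, 2.42 and 4.36 for AT3G15670, 2.57 and 4.94 for AT4G36600, and 2.49 and 4.05 for LEA4-5. For LTI30 it was 3.23 and 3.19, and for AT2G42560 3.87 and 4.44. AT3G17520 differed by 4.73 with a standard error of 1.16, and AT2G42560 by 4.16 with a standard error of 1.07. The dehydrin COR47 was higher by 0.95 with a standard error of 0.97, within its spread. The member that ran the other way was AT1G54410 (the dehydrin HIRD11), with a log2 difference of -0.85 and both TSA arrays below both untreated arrays. AtLEA4-1 was high in TSA replicate 1, at a signal of 29126, and at 1242 in TSA replicate 2, against 1504 and 1700 in untreated seeds.

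**Figure D1:**
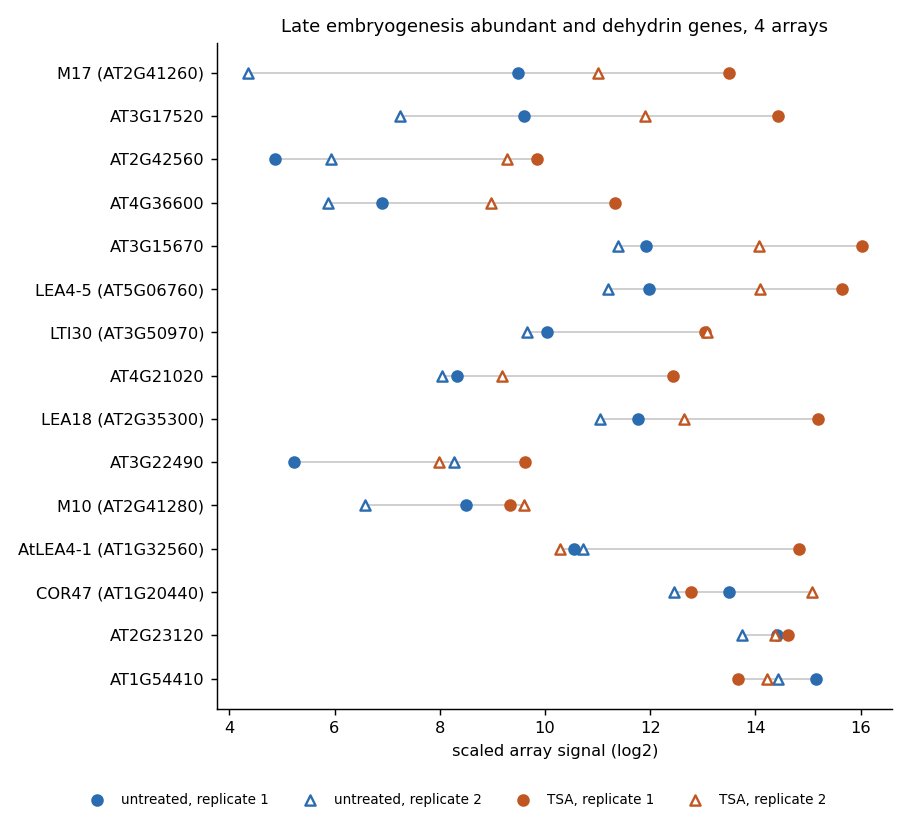
Scaled array signal (log2, horizontal axis) of the 15 measured late embryogenesis abundant and dehydrin genes, ordered by their mean difference. Circles are replicate 1 and triangles replicate 2, orange is TSA and blue untreated, and the grey line spans the 4 arrays. In 10 genes both TSA points lie to the right of both untreated points.

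Transcripts of other seed reserves had too few members past the intensity filter for a test. The cupin-type storage protein genes AT4G36700 and AT2G28490 were 7.08-fold and 8.5-fold higher in TSA, and the oleosin genes AT2G25890 and OLEO3, which code for proteins that coat seed oil bodies, 7.32-fold and 6.25-fold. In all 4 both TSA arrays lay above both untreated arrays, and on all arrays none passed limma's adjusted threshold over all probe sets. A further storage gene, the cupin AT1G03890, fell under the intensity filter. Its groups overlapped, with signals of 352 and 89.1 in TSA against 42.9 and 168 in untreated seeds. Its differences were 3.04 in pair 1 and -0.92 in pair 2. Adjusted over the list alone, 2 of 2 storage genes and 0 of 2 oil body genes passed. The storage genes no longer passed when TSA replicate 1 or either untreated array was left out. The median difference of the storage genes was 4.12 in pair 1 and 1.79 in pair 2, and that of the oil body genes 4.16 and 1.36. Over all arrays these medians were 2.96 and 2.76. They were 1.60 and 1.17 without TSA replicate 1 and 4.31 and 4.35 without TSA replicate 2, moves of over 1.5 times in fold. The glyoxylate cycle enzyme ICL (isocitrate lyase) and AIM1, from the list of lipid mobilisation, differed by 0.72 and 0.49, with standard errors of 1.08 and 0.66.

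Photosynthesis genes showed no common shift between the groups, and the TSA arrays lay on opposite sides of the untreated ones. Over 7 photosystem genes the median difference was -0.60, with a camera adjusted p of 0.584 (0.855 with an estimated correlation). In pair 1 the median was -3.72 and 6 of the 7 were lower in TSA, and in pair 2 it was 2.48 and 7 were higher. LHB1B2 (LHCB1.5), a light-harvesting chlorophyll-binding protein of photosystem II, had a signal of 34.7 on TSA replicate 1 and 69501 on TSA replicate 2, against 7966 and 9151 in untreated seeds. PSAN, a photosystem I subunit, had 140.5 and 23061 against 6148 and 2455. LHCB4.1 had 1352 and 105665 against 21120 and 19243, while LHCB4.3 had 767.8 and 750.3 against 640.9 and 660.3. The 3 Calvin cycle genes, PRK (phosphoribulokinase), SBPASE (sedoheptulose-bisphosphatase) and RCA (rubisco activase), had a median difference of 0.09 over all arrays, of -2.09 in pair 1 and of 2.28 in pair 2 (camera adjusted p = 0.982; 0.991 with an estimated correlation). Leaving out either TSA array gave both lists a median larger in size, in opposite directions. Without TSA replicate 1 the photosystem median was 2.39, and without TSA replicate 2 it was -3.63. The Calvin cycle medians were 2.21 and -1.91. On all arrays, no member of either list passed, whether adjusted over all probe sets or over the list alone. Calls in the fits without 1 TSA array are not given, since their spread comes from the untreated arrays alone.

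**Figure D2:**
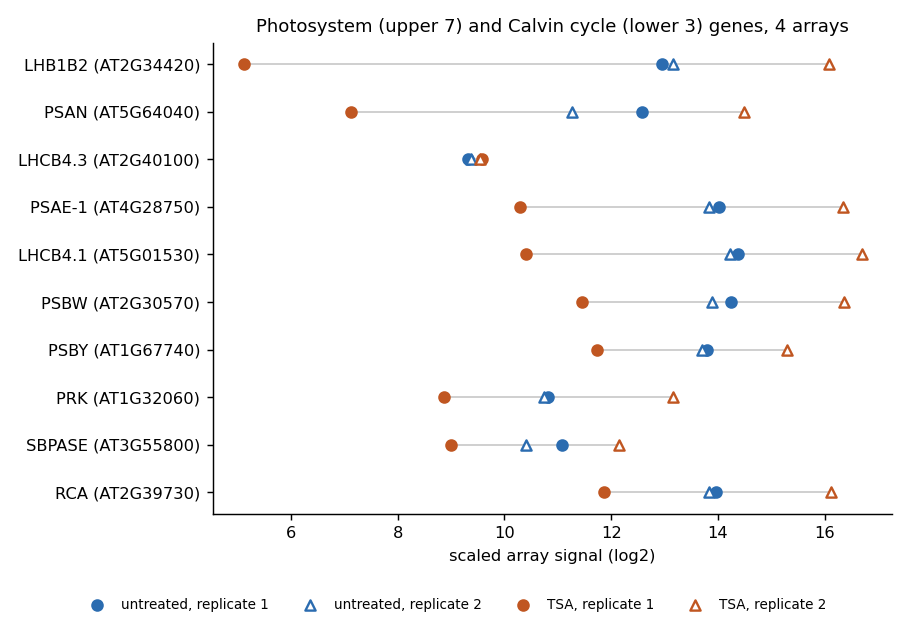
Scaled array signal (log2, horizontal axis) of 7 photosystem genes (upper rows) and 3 Calvin cycle genes (lower rows) on each array. Circles are replicate 1 and triangles replicate 2, orange is TSA and blue untreated. TSA replicate 1 lies below both untreated arrays in 9 of the 10 genes and TSA replicate 2 above both in 10.

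The 8 histone genes measured had a median difference of -0.45 (mean -0.03; camera adjusted p = 0.584; 0.855 with an estimated correlation), of 0.25 in pair 1 and -0.70 in pair 2. Of these, 7 had the lower mean in TSA, among them HIS4 (histone H4) at -0.90, AT2G30620 (a linker histone) at -0.60 and AT2G28720 (histone H2B) at -0.36. HIS4 differed by -0.18 in pair 1 and by -1.62 in pair 2. HIS1-3, a linker histone known to be induced by drought, was 9.74-fold higher in TSA, at log2 9.42 ± 0.20 against 6.14 ± 1.84 (SD, n = 2). Its untreated signals were 173.4 and 28.5, and its log2 difference of 3.28 was 4.59 without untreated replicate 1 and 1.98 without untreated replicate 2. Adjusted over the list alone, 0 of the 8 passed. Without TSA replicate 1 the histone list had a median of -0.87, and without TSA replicate 2 the median was 0.26.

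Among 5 expansin and xyloglucan endotransglucosylase genes, which act on the cell wall, the median difference was 0.48 (camera adjusted p = 0.0596; 0.387 with an estimated correlation). Pair 1 gave 0.55 and pair 2 gave 0.22. The expansin EXPA8 was 5.94-fold higher in TSA, at 13.19 ± 0.40 against 10.62 ± 0.28 (SD, n = 2), and was the 1 member that passed when adjusted over the list alone. No member did so without untreated replicate 1 or without untreated replicate 2, or when array medians were set equal. XTH33, EXPA15 and EXGT-A3 differed by 1.18, 0.48 and 0.28, each by less than 1.5 standard errors. The difference of XTH33 was -0.04 in pair 1 and 2.39 in pair 2. The 3 heat shock protein genes had a median of 0.44 (camera adjusted p = 0.0796; 0.387 with an estimated correlation), of 1.05 in pair 1 and 0.04 in pair 2. The small heat shock protein gene AT1G53540 was 5.27-fold higher, and AT1G59860 and AT3G09440 differed by 0.39 and 0.44. Of 4 tubulin genes, TUB5 and TUB9 differed by -1.13 and -0.53 and TUA1 and TUB6 by 0.86 and 0.15. Their median was -0.19 over all arrays, -0.29 in pair 1 and -0.08 in pair 2 (camera adjusted p = 0.777; 0.855 with an estimated correlation). No heat shock or tubulin gene passed when adjusted over the list alone, except 1 heat shock gene in the fit without the intensity trend.

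Other lists had 1 measured member or none. EEL, a bZIP factor of seed maturation, differed by 0.66, the cold- and abscisic acid-responsive KIN2 by 0.76, the gibberellin signalling F-box gene SLY1 by 0.24, the glutathione transferase GSTF3 by 0.34 and the defensin LCR67 by 0.64. PRL, a subunit of the replication licensing complex, differed by -1.12. In each of these 6 the difference was smaller than its standard error. The lists of histone deacetylases and acetyltransferases, root hair markers and floral organ identity had no member with a named probe set. The list of phenylpropanoids and flavonoids had 2, both under the intensity filter.

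Outside the lists, the genes with the smallest limma p among those without overlap between groups were also named by the rule. Those higher in TSA were AT4G31830 (35.1-fold), AT1G05340 (6.79-fold), AT2G44830 (6.6-fold), AT2G21820 (6.53-fold) and AT4G25580 (14.9-fold). Without TSA replicate 1 and without TSA replicate 2, the log2 difference was 3.94 and 6.33 for AT4G31830, 2.74 and 5.06 for AT4G25580, 1.84 and 3.58 for AT2G21820, 3.46 and 2.07 for AT1G05340, and 2.47 and 2.98 for AT2G44830. Of those lower in TSA, the class III peroxidase gene AT5G64100 was 6.93-fold lower, at 12.28 ± 0.23 against 15.07 ± 0.18 (SD, n = 2), and the peroxidase gene AT1G30870 was 12.3-fold lower. XTH26, a xyloglucan endotransglucosylase outside the fixed list, was 29.7-fold lower, with signals of 22.8 and 592 in TSA against 4003 and 2976. The beta-glucosidase BGLU15 was 7.59-fold lower and sks16, of the multicopper oxidase-like SKU5 family, 5.86-fold. AT4G34800 (SAUR4, of a family of auxin-responsive transcripts) was 4.4-fold lower. The others were AT1G52070 (78.4-fold), AT4G33730 (10.4-fold), AT2G45750 (6.31-fold), AT1G30990 (6.04-fold), AT2G17850 (5.84-fold) and AT4G33560 (4.82-fold). The fold of AT1G52070 rests on a signal of 8.2 on TSA replicate 1, under that array's 5th percentile of 13.8: its log2 difference of -6.29 was -3.20 without TSA replicate 1, -9.39 without TSA replicate 2 and -4.84 with an offset of 50 on the signal. XTH26 likewise gave -2.54 and -7.24 without TSA replicates 1 and 2, AT4G33730 -1.88 and -4.89, AT1G30870 -2.11 and -5.13, BGLU15 -1.97 and -3.88, and AT2G45750 -2.01 and -3.30. Of the 24 genes with the smallest p at both ends, list members included, 14 moved by over 1.5 times in fold when 1 array was left out. Each of these 17 genes outside the lists had a limma adjusted p of 0.9999.

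Across all 5498 probe sets, limma called 0 at the adjusted threshold, with a lowest adjusted p of 0.576. At an unadjusted p under 0.05 there were 140, 88 higher and 52 lower in TSA, where chance alone gives 275. Groups did not overlap in 25.3% of probe sets, against 33.3% by chance. The probe set with the lowest p was 51-fold higher in TSA and is unnamed here, and the unnamed one with the lowest p among those lower in TSA was 25.7-fold lower. Of the alternative fits, only that without TSA replicate 2 had calls. Its spread comes from the 2 untreated arrays alone, so its calls show how far TSA replicate 1 lay from untreated seeds.

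The TSA arrays were the least alike of all pairs of arrays. Their log2 signals correlated across probe sets at r = 0.586, with 1178 probe sets over 4-fold apart, and those of the untreated arrays at r = 0.855, with 368. Across the probe sets, the TSA minus untreated differences of pair 1 and pair 2 correlated at r = -0.125 (rho -0.119; genes are not independent replicates). In 46 probe sets TSA was over 4-fold higher in both pairs, and in 18 over 4-fold lower in both. In 92 it was over 4-fold lower in pair 1 and over 4-fold higher in pair 2, and in 17 the other way.

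**Figure D3:**
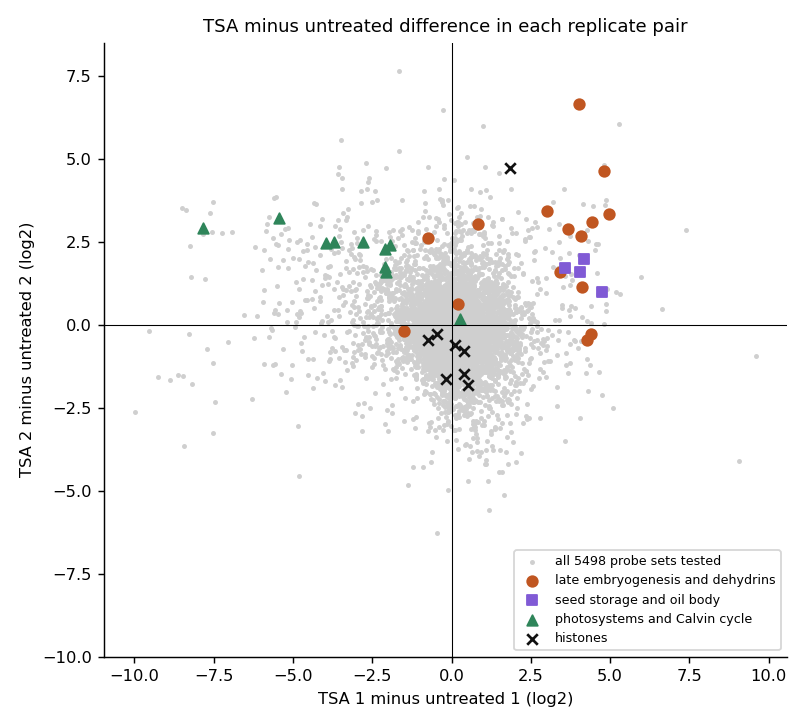
TSA minus untreated log2 difference of each tested probe set in replicate pair 1 (horizontal axis) and replicate pair 2 (vertical axis). Grey points are all 5498 probe sets and coloured symbols the members of fixed lists. Late embryogenesis genes lie mostly at the upper right, with medians of 4.01 and 2.68, and photosystem genes at the upper left, with medians of -3.72 and 2.48.

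Replicate number also separated the arrays by their control probe sets. The median signal of 12 probe sets for poly-A control transcripts was 29.3 on TSA replicate 1 and 90.8 on untreated replicate 1, against 8433 and 7549 on replicate 2 of TSA and untreated. The 25S ribosomal RNA probe set read 1639 and 229.1 on the arrays of replicate 1, TSA first, and 25345 and 72300 on those of replicate 2. Each such batch held 1 array of either group. With the replicate number as a block, limma again called 0 probe sets, with 168 at an unadjusted p under 0.05.

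**Figure D4:**
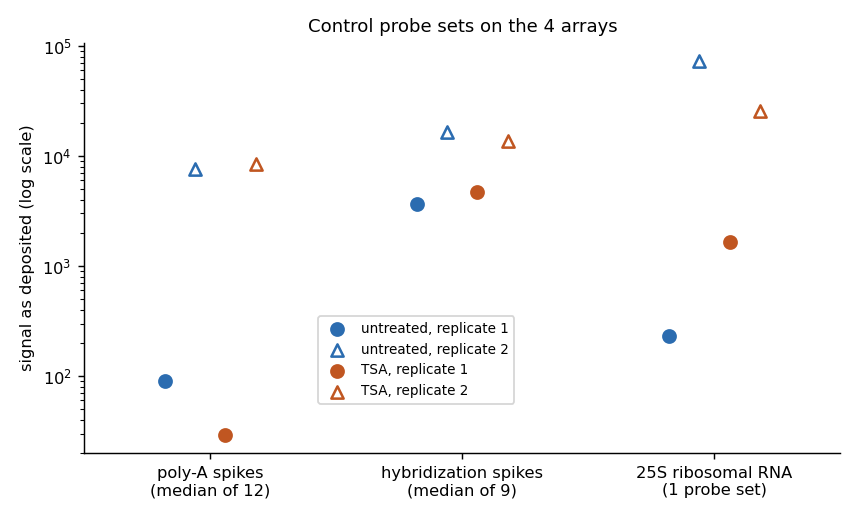
Signal as deposited (log scale, vertical axis) of 3 kinds of control probe sets on each array. Circles are replicate 1 and triangles replicate 2, orange is TSA and blue untreated, and points are medians over 12 and 9 probe sets or the value of 1. The poly-A controls read 29.3 and 90.8 on replicate 1 and 8433 and 7549 on replicate 2.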

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

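The alternatives were chosen before the data were examined. The count of probe sets past limma's adjusted threshold was 0 under every alternative with the adjusted test except the fit without TSA replicate 2, so that leaving out an array gave between 0 and 193. An adjusted p under 0.1 also gave 0. A rule of at least 2-fold and no overlap, with no test, gave 606, 372 higher and 234 lower. Unadjusted p under 0.05 gave between 66 (without untreated replicate 1) and 681 (without TSA replicate 1). With the replicate block limma called 0, and 134 probe sets had an unadjusted p under 0.05 in both fits. The block changed no list call either: 1 list was called. The control probe sets separate the arrays by replicate number, while the labels do not say that a number marks a shared day. A fit without 1 array assumes that the lone array of a group varies like the others. The TSA arrays varied more, with a median SD of 0.69 against 0.45 between the untreated arrays.

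The number of lists called by camera was 1, and it was 0 with an estimated correlation, 2 with no filter on dim probe sets, 3 without the intensity trend, and 1 to 4 when an array was left out. The late embryogenesis list kept its direction in every alternative and its call in all but the estimated correlation (median 2.62, adjusted p 0.387). Its medians without an array ran from 2.09 to 4.05. The expansin list passed with no filter (0.48, adjusted p 0.0331) and without the trend (0.48, adjusted p 0.0497), where heat shock proteins passed too (0.44, adjusted p 0.0497). The causes were not tested. With the stricter filter heat shock proteins had too few members for a test. With an array left out, medians ran from -3.63 to 2.39 for photosystems, -1.91 to 2.21 for the Calvin cycle, -0.87 to 0.26 for histones, 0.18 to 0.77 for expansins, 0.36 to 1.1 for heat shock proteins and -0.35 to 0.013 for tubulins. Under quantile normalization the Calvin cycle median, that of RCA, turned to -0.0059. Other scalings moved the median of all probe sets by less than 0.1 on the log2 scale. The values as deposited differ from the scaled ones by almost nothing, so that alternative tests nothing, and the robust fit does not enter camera.

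The 24 genes at both ends kept their sign in every alternative that kept their probe set. They had been chosen with both TSA arrays on one side of both untreated arrays. Leaving out an array therefore could not turn a sign, and the kept signs are no evidence of a stable effect. Leaving out 1 array moved the fold of 14 by over 1.5 times, and of AT1G52070 by up to 8.55 times. Without TSA replicate 2, 17 named genes passed the adjusted threshold, against 0 in all other alternatives. Among list members, signs turned when an array was left out, with ranges of -7.94 to 3.03 for LHB1B2, -4.79 to 2.57 for PSAN, -3.90 to 2.39 for LHCB4.1, -1.76 to 1.4 for SBPASE, -0.75 to 1.70 for EXPA15, -0.22 to 1.1 for AT3G09440, -1.91 to 2.39 for PRK, -2.04 to 2.21 for RCA, -0.36 to 0.66 for TUB6 and -0.25 to 1.03 for AT1G59860. No detection calls were used, so how far dim signals lie above background is unknown.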

Other observations

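All tests in this part were chosen after the results had been seen. Those of an exchanged array and of an earlier stage replaced first versions that counted genes (11 of 15 and 15 of 19). The outcomes were the same. The test of RNA degradation first read 1 control ratio and then both, which left it open. Genes in which TSA differed over 4-fold from untreated in both replicate pairs were also chosen after their values were seen. Of 46 such probe sets that were higher, 21 carried a name, and 7 of these genes belong to the late embryogenesis list. The storage and oil body genes fell short of 4-fold in pair 2. Others were ATOEP16-2, an outer envelope protein gene, with differences of 3.72 and 2.69, GLR3.5, a glutamate receptor-like channel gene, with 3.39 and 2.48, and UBP18, a ubiquitin-specific protease gene, with 2.02 and 2.14. Of the 18 that were lower, 8 carried a name, among them AT4G22460 with -2.40 and -2.05 and AT2G33710 with -2.01 and -2.08.

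In 92 probe sets TSA was over 4-fold lower in pair 1 and over 4-fold higher in pair 2. The 31 that carried a name stood for 28 genes, 6 of them from the photosynthesis lists. Outside those lists, WRKY29, a transcription factor gene, differed by -5.77 and 3.25, and ECS1 by -5.60 and 3.81. The opposite pattern held for 17 probe sets, 5 of them named, with AT1G04660 at 9.05 and -4.09.

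There are 3 ways to divide 4 arrays into pairs, too few to exclude chance. Probe sets with an unadjusted limma p under 0.05 numbered 140 for TSA against untreated, the fewest of the 3. They numbered 453 for replicate 1 against replicate 2, and 163 for the division that mixes both groups and both replicates. The late embryogenesis list had a camera adjusted p of 2.5e-14 for TSA against untreated and was the 1 list called there. That call was lost with an estimated correlation (camera adjusted p 0.387). Replicate 1 against replicate 2 called 3 lists, photosystems and histones each with an adjusted p of 0.0279 and the late embryogenesis list with 0.0427. The division that mixes both groups and both replicates called photosystems with an adjusted p of 1.15e-05 and the Calvin cycle with 0.00127. At the preset correlation, camera therefore also called lists in divisions that do not follow the treatment.

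The photosynthesis genes were low in TSA replicate 1 and high in TSA replicate 2, with a median difference of -4.61 between these arrays over 10 genes. The batch alone is argued against, since the untreated arrays of the same batches differed by a median of 0.14. For an exchange of TSA replicate 2 with an untreated array, the late embryogenesis genes were read. On TSA replicate 2, 11 of 15 were above both untreated arrays. Their median there lay 1.53 above the brighter untreated array, more than the 0.73 between the untreated arrays. In 10 of these genes both TSA arrays had already been seen above both untreated arrays. The outcome was thus largely known beforehand, and the test cannot decide on an exchange. Neither control ratio of 3' over 5' signal was raised in TSA replicate 1 over untreated replicate 1. That of GAPDH was 0.646 against 1.48, the lowest of the 4 arrays. That of ubiquitin was 2.96 against 2.97 (2.19 and 2.08 on the arrays of replicate 2). RNA degradation in TSA replicate 1 stays open, since 2 ratios on 1 array are too few to exclude it. A candidate explanation is that seeds of TSA replicate 1 were at an earlier stage than those of replicate 2. Late embryogenesis, storage and oil body genes exceeded untreated by more in pair 1 than in pair 2 (percentile 99.8 of matched random lists). These lists were already higher in TSA, so any larger TSA difference in pair 1 would pass, and the test cannot decide on stage. TSA replicate 1 was above TSA replicate 2 in 15 of these 19 genes. Untreated replicate 1 was also above untreated replicate 2 in 14. In 7 of 8 histone genes TSA replicate 1 was above TSA replicate 2 as well (median 0.94, against 0.53 between the untreated arrays). PRL read 5009 and 375 on TSA replicates 1 and 2, against 3649 and 2421 in untreated seeds. Histones and PRL did not enter the test of stage. A dose that differed between the treatments was not tested.

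For the higher late embryogenesis genes, a plain arrest before photosynthesis genes are expressed is argued against for TSA replicate 2, where the photosynthesis genes lay above untreated replicate 2 by a median of 2.44. For TSA replicate 1, where they lay below untreated replicate 1 (median difference -2.45), such an arrest may apply and stays open. Histone genes had a median difference of 0.25 in that pair and PRL one of 0.46, and neither was set against an arrest.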
